A study of Homo sapiens with 32 samples.

How the data were processed

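Per the labels, all 32 libraries came from COLO205, an established human colon adenocarcinoma cell line. Total RNA was sequenced in 24 libraries, 3 in each of 8 groups. One table held unmodified cells (WT), cells with a CRISPR-inserted tag in exon 1 of PIWIL1 (TAG) and a pair of CRISPR knockouts of PIWIL1 (KO1 and KO2). The other table held cells with a retroviral control short hairpin RNA (CTRL) or with short hairpin 1, 2 or 3 against PIWIL1 (SH1, SH2 and SH3). Small RNA was sequenced in 8 libraries. In 4 of them it was recovered with Flag-tagged PIWIL1 by immunoprecipitation (IP), 1 was labelled as the background of that immunoprecipitation, with the same tagged genotype and no word on how it differed, and 3 held size-selected small RNA of wild-type cells (sRNA). Per the labels' protocols, RNA was extracted with a Zymo Direct-Zol kit, long RNA libraries were made with a NEBNext Ultra II kit, and small RNA libraries by ligating adapters to both ends, reverse transcription and PCR. Every library was placed in its group by its title and genotype label, and every column of per-library values matched 1 library. Where replicates were grown is not given in the sources used here, so p-values measure only the spread between these libraries, which may be technical.

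The submitters' processing notes name cutadapt 1.16, STAR 2.5.2b, HISAT2 2.2.1.0, StringTie 1.3.4d and the genome build hg38, without saying which tool made which file. The authors deposited gene levels as TPM, a transcript abundance scaled for length and library, in a table of the knockout experiment and a table of the hairpin experiment. The listed genes summed to between 978643 and 986151 TPM per library in the first and between 945710 and 980231 in the second, so some features were dropped after scaling. TPM keeps no depth, so the number of reads behind a gene level is unknown. The authors deposited whole-number counts per repeat family for the same 24 libraries. How reads mapping to several places were assigned, and whether strand was used, is not given in the sources used here. For small RNA the authors deposited counts of reads per read length and, per the file headers, a library size ratio to the background library or a ratio of miRNA counts to the first sRNA library. A deposited signal per read length held those counts divided by these ratios, which was checked on the values. The deposited annotation table held normalized read numbers per class, which the authors had rounded to whole numbers, so these were treated as a score and only shares within a library were taken from them. Gene and repeat tables of the 2 experiments were treated as normalized separately, and their levels were tested only within 1 table.

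Gene levels were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the prior. Genes with at least 1 TPM in at least 3 libraries entered the fit, 17197 in the knockout table and 14283 in the hairpin table, and the 12 libraries of a table shared 1 estimate of the spread. A fold change on this scale understates the change of genes with low levels. Repeat counts were tested with edgeR 4.0.16 by the quasi-likelihood test after TMM scaling and the default filter on low counts, which left 1023 transposon families and 67 other repeats in the knockout table and 990 and 52 in the hairpin table. Benjamini-Hochberg adjustment was applied over all features of a fit, and an adjusted p under 0.05 counted as a change. A change common to both knockouts, or to all 3 hairpins, had to pass in each comparison with the same sign. The mean of the knockouts, or of the hairpins, was also set against its control as 1 contrast. Gene lists and transposon lists were tested with camera, a competitive test of a list against all other features, with a preset correlation of 0.01 and again with a correlation estimated from the residuals. Lists needed at least 3 tested members. Beside each list's count over all features, a count adjusted over the list alone was taken. Shared controls were examined by simulating 20 sets of unchanged groups against the same control libraries. Shares of small RNA reads were compared with an exact permutation test in SciPy 1.17.1, two-sided, under Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. A share from a single library has a 95% exact Clopper-Pearson interval, which covers counting error only, since PCR reads without molecular identifiers are not independent molecules.

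Groups, comparisons, tests, alternatives and the lists of 22 gene groups and 7 transposon groups were fixed before the data were examined. The gene lists covered the piRNA pathway, the miRNA pathway, transposon restriction, germline and cancer-testis genes, the interferon response, proliferation, epithelial adhesion, mesenchymal genes, colon epithelium, WNT targets, p53 targets, unfolded protein and amino acid stress, heat shock, hypoxia and glycolysis, cholesterol synthesis, NF-kB and inflammatory genes, immediate early genes, KRAB zinc finger genes, replication-dependent histones, mitochondrially encoded genes, ribosomal proteins, and markers of fibroblasts, endothelium and immune cells. The transposon lists covered young LINE-1, young Alu, SVA, HERV-K (HML-2), HERV-H, HERV-9 with LTR12, and primate-specific LTRs, and every repeat class and every family group with at least 5 tested members was added. The named genes were also set by rule. PIWIL1 and the piRNA pathway came first. In each experiment up to 12 genes higher and 12 lower in every arm were taken, with a mean of at least 5 TPM and ranked by the smallest change among the arms. For TAG and each single arm the 6 higher and 6 lower with the largest change were taken under the same minimum. Each list added up to 4 members with the smallest p in the mean contrast and up to 2 with the highest control level. Transposon families were named by the same rule with 8 in place of 12 or 6, and every family of a transposon list was eligible. Clone and locus identifiers were counted and not named, and 1 gene that the rule took is not reported here, although counts include it.

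Alternatives to the gene fit were a pseudocount of 0.1 or 5, no filter on low values, quantile normalization, the replicate number as a block, and only the libraries compared in the fit. For the repeat counts they were DESeq2 1.42.0, its size factors within edgeR, total counts without TMM, no filter, the block and only the libraries compared. Other alternatives were TAG in place of WT as the control, each replicate left out in turn, other read length ranges, and for list tests the estimated correlation and the block. Robust empirical Bayes moderation, the repeat fit without MER11B, the small RNA range of 25 nt or more, the list tests without KO2 replicate 2 or SH2 replicate 3, the PIWIL1 tests without SH2 replicate 3 and the exact permutation tests of PIWIL1, with and without SH2 replicate 3, were added after the data were seen. PIWIL1 was located with a RefSeq gene table of assembly GRCh38.p14, which is of the build family hg38.

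The procedure was tested on simulated data with 200 changed features, 100 at each of 2 sizes. Changed genes were drawn only from those with a control level of at least 5 TPM, so recovery of genes below that is not known. For KO1 against WT over 17197 genes, 19% of genes changed by 0.5 on the log2 scale and 92% of genes changed by 1 were recovered, with 6 false calls. For SH1 against CTRL over 14283 genes, the values were 21%, 87% and 3 false calls. Over 1090 repeats for KO1 against WT, 85% and 97% were recovered with 12 false calls. Over 1042 repeats for SH1 against CTRL, 64% and 87% were recovered with 8 false calls. No 2 libraries of a group agreed within sampling noise in their repeat counts, so none was counted as a duplicate. Among genes with a median of at least 5 TPM, 28 of 9914 in the knockout table and 20 of 7992 in the hairpin table were listed at 0 in some library, including FBL, a nucleolar protein gene every cell uses, so an exact 0 may be a failed estimate. Histone genes, AKR1C1 with AKR1C2, PRSS1 with PRSS2 and other near-identical copies may share reads, and readthrough or overlapping models (ZNF664, TMEM189, C7orf55-LUC7L2) may split them, so their single values are uncertain.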

Results

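PIWIL1 is a germline member of the PIWI proteins, which bind small RNAs called piRNAs and silence transposons in germ cells. The series asked whether the PIWIL1 made in COLO205 colon adenocarcinoma cells carries small RNAs with piRNA features, and how genes and transposons respond when PIWIL1 is knocked out or knocked down. The knockout table listed 38762 genes over 12 libraries (WT, TAG, KO1 and KO2). The hairpin table listed 37463 over 12 (CTRL, SH1, SH2 and SH3). Repeat counts per library ran from 5491844 to 7574227 in the knockout table and from 1127757 to 2116262 in the hairpin table, so repeats were measured less precisely in the latter. The 2 tables were normalized separately and differed in makeup. Mitochondrially encoded genes took 2.40% to 4.76% of the TPM in knockout-table libraries and 20.1% to 25.2% in hairpin-table libraries, and RN7SL transcripts took 17.1% to 26.4% and 14.1% to 20.2%. The number of genes with at least 1 TPM was 15781 ± 141 in WT, 16316 ± 99.3 in KO1 and 15150 ± 614 in KO2 (mean ± SD, n = 3).

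PIWIL1 (ENSG00000125207.7) lies on chromosome 12 from 130337887 to 130426260 in GRCh38.p14 and is a protein-coding gene. Its transcript was measured in every long RNA library. It stood at 36.5, 38.9 and 37.0 TPM in the WT libraries (37.5 ± 1.25, SD, n = 3) and at 40.9 ± 1.56 TPM in TAG, a log2 difference of 0.12 ± 0.12 (SE, limma adjusted p = 0.62). KO1 held 26.3 ± 0.38 TPM, lower than WT by a log2 value of -0.49 ± 0.12 (limma adjusted p = 0.043). The KO2 libraries held 33.7, 25.8 and 37.6 TPM, and their log2 difference of -0.22 ± 0.12 did not pass (limma adjusted p = 0.37). Over both knockouts, 5 of 6 libraries lay below every WT library, with an exact two-sided permutation p of 0.0714, the smallest possible being 0.0238. The call in KO1 ended when any of its 6 libraries was left out. Transcript levels do not show protein, which was not analysed, so they check the knockout labels only in part.

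In the hairpin table PIWIL1 stood at 18.7 ± 0.63 TPM in CTRL. SH1 held 4.53, 6.83 and 8.40 TPM, SH2 held 6.93 and 10.6 TPM with its replicate 3 listed at 0.00, and SH3 held 9.02 ± 0.24 TPM. Since an exact 0 may be a failed estimate, that library was left out here. The other 8 hairpin libraries lay below every CTRL library, the highest at 10.6 TPM against a lowest CTRL value of 18.0 TPM. Their mean log2 difference was -1.15, with an exact two-sided permutation p of 0.0121, the smallest that 165 splits can give. With the library listed at 0 the values were -1.50 and an exact permutation p of 0.00909, the smallest that 220 splits can give. The limma fit over all 12 libraries gave log2 values of -1.41 for SH1, -2.13 for SH2 and -0.97 for SH3, each ± 0.68 (SE), and none passed (adjusted p = 0.43, 0.25 and 0.59). That error came from the library listed at 0. Without SH2 replicate 3, SH1 and SH3 passed (limma adjusted p = 0.011 and 0.034), and the value for SH2 was -1.04 (limma adjusted p = 0.081).

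**Figure D1:**
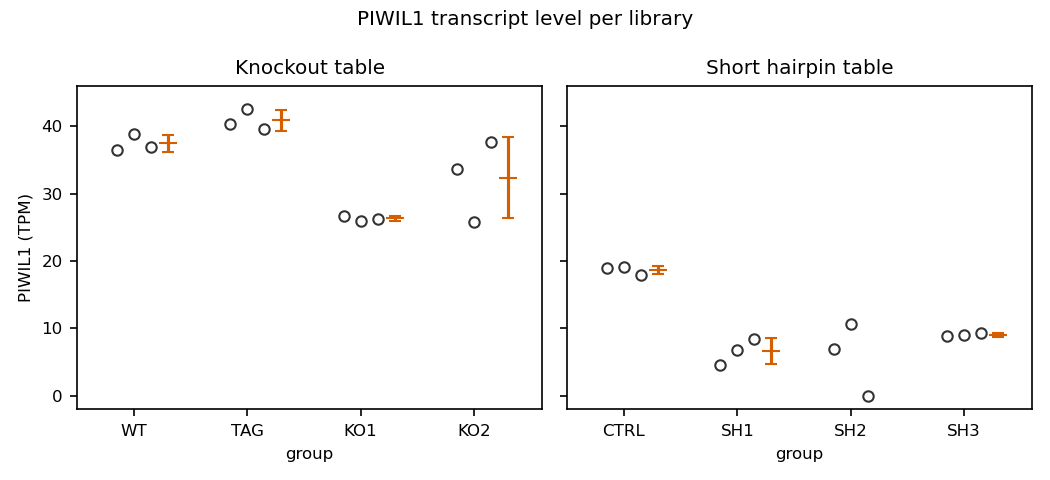
PIWIL1 transcript level (TPM, vertical axis) in each long RNA library of the knockout table (left) and the hairpin table (right), with circles for libraries and a bar with whiskers for the mean ± SD of a group (n = 3). No mean is drawn for SH2, whose replicate 3 is listed at 0.00, and the other 8 hairpin libraries lie below the lowest CTRL value of 18.0 TPM.

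Other genes of the piRNA pathway were mostly silent. Of 36 genes fixed for this pathway, 23 were listed in the knockout table and 8 reached a WT mean of 1 TPM. These were PRMT5 at 54.5 TPM and its partner WDR77 at 18.1 TPM, which act widely in arginine methylation, PIWIL1 itself, TDRD3 at 14.4, TDRKH at 10.6, HENMT1 at 10.5, TDRD7 at 5.07 and PLD6 at 1.45 TPM. TDRKH, HENMT1 and PLD6 take part in piRNA maturation in germ cells. PIWIL4 stood at 0.90 TPM and PIWIL2 at 0.15 TPM. In CTRL, 26 were listed and 9 reached 1 TPM, PIWIL4 among them at 1.60 TPM. Among the 9 pathway genes tested in each table, PLD6 rose in KO1 by 0.51 ± 0.11 (limma adjusted p = 0.028). In the mean contrasts none changed over all genes tested, with 1 lower among the knockouts and 0 in the hairpin table when adjusted over the list alone, and the list test gave adjusted p = 0.81 and 0.15. For the knockouts the list's median was 0.06 and its mean -0.00, and for the hairpins the median was -0.00 and the mean -0.19, a mean that includes PIWIL1. Of the germline and cancer-testis list, only REC8 and STAG3 entered a test, so the list had too few members.

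Tagging PIWIL1 was compared with WT to see how far the tagged line, the source of the immunoprecipitates, had moved from its parent. PRR9, a gene of the epidermal differentiation region, fell from 40.6 ± 2.47 to 1.48 TPM in TAG, a log2 value of -4.07 ± 0.11. AKR1B10, an aldo-keto reductase, fell from 31.8 to 4.01 TPM (-2.72 ± 0.13), and CA9, a hypoxia-induced carbonic anhydrase, from 28.2 to 4.10 TPM (-2.52 ± 0.12). SLC9A3, a sodium-proton exchanger, SPRR1A, a cornified envelope protein, and SLC28A2, a nucleoside transporter, fell by 1.83, 1.74 and 1.70 on the log2 scale. Higher in TAG were SCRN1 (1.75 ± 0.19), SMOC2, a matricellular protein, from 13.7 to 42.9 TPM (1.58 ± 0.10), the desaturase SCD5 (1.51), PLEKHB1, KLHL24 and DZIP3. Of 17197 genes tested, 1120 changed, 614 higher and 506 lower, which is 6.51%. With quantile normalization the split was 1202 higher and 1268 lower.

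Among the fixed lists, colon epithelium genes were lower in TAG, with 8 of 23 lower and 1 higher (11 and 3 adjusted over the list alone). FABP1, a fatty acid binding protein of enterocytes, fell by 1.93 ± 0.24, and KRT18, an epithelial keratin, by 0.44 ± 0.12. Ribosomal protein genes fell in 6 of 61 cases (8 adjusted over the list alone), RPL18 by 0.72 ± 0.11, and none rose. Stress genes of the unfolded protein and amino acid responses rose in 5 of 24 cases and fell in 1 (9 and 1 adjusted over the list alone), DDIT4 among the higher at 0.43 ± 0.10. KRAB zinc finger genes rose in 3 of 20 cases and fell in 1 (6 and 1 adjusted over the list alone), and transposon restriction genes rose in 4 of 31 (6 adjusted over the list alone). None of the 13 heat shock genes changed, also adjusted over the list alone, while their median was -0.19. Among the 4 tested markers of fibroblasts, endothelium and immune cells, LYZ, a lysozyme that intestinal epithelium also makes, fell by 0.67 from 592 TPM and HBA1 by 1.12 (2 adjusted over the list alone). The camera tests of these 7 lists passed, in the order given with adjusted p = 1.0e-06, 5.1e-08, 0.0029, 0.0029, 0.033, 0.0015 and 0.0045. All 7 were lost, at adjusted p = 0.76, 0.83, 0.94, 0.76, 0.94, 0.82 and 0.24 with an estimated correlation. Leaving out any 1 of the 6 libraries except TAG replicate 3 lowered the count of 1120 genes to between 536, without WT replicate 1, and 725, without WT replicate 3.

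Knockout of PIWIL1 was compared with WT for genes that moved the same way in both lines. PRR9 rose from 40.6 ± 2.47 TPM to 87.5 in KO1 and 104.5 in KO2, log2 values of 1.09 and 1.34, each ± 0.11. SLC12A2, a sodium-potassium-chloride cotransporter, rose by 1.12 and 0.98 from 56.3 TPM, and PCK1, a gluconeogenic enzyme, by 0.67 and 0.95, each ± 0.12. LEF1, a transcription factor of WNT signalling, rose from 2.48 ± 0.21 TPM to 14.7 ± 1.44 in KO1 (2.17 ± 0.11) and to 4.19 ± 0.34 in KO2 (0.57 ± 0.11). The chemokine CCL24 (6.72 and 9.64 TPM from 3.74), the adaptor NEDD9 (0.68 and 0.87), the BCL2 family member BOK (0.82 and 0.62), MORC4, ID2, TSEN54, the chaperonin subunit CCT2 and MYCN were also higher in both, the last at 6.07, 9.45 and 8.99 TPM in WT, KO1 and KO2.

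TFF1, a secreted trefoil peptide of mucus, fell from 17.8 ± 1.66 TPM to 4.72 in KO1 and 4.14 in KO2 (-1.72 and -1.88, each ± 0.16). AGT, which encodes angiotensinogen, fell by 1.76 and 1.03, and the chloride transporter SLC26A9 by 1.24 and 0.90. The immediate early genes EGR1 and IER2 were lower in both. EGR1 stood at 182 ± 9.66 TPM in WT, 98.0 ± 8.12 in KO1 and 60.8 ± 8.62 in KO2. HLA-B, an MHC class I heavy chain with near-identical relatives, fell from 15.9 ± 1.02 TPM to 6.76 (adjusted p = 3.4e-04) and 8.99 (limma adjusted p = 0.0035). TFEB, a regulator of lysosomal genes, fell by 1.12 and 0.82, and IGFL1P1, HIST2H3PS2, MDFI, ACY3 and GGT1 were lower in both by 0.77 or more. Several of these genes also differed between TAG and WT, neither of them a knockout of PIWIL1. TFF1 was lower in TAG by 0.96 and AGT by 0.95, LEF1 was higher by 0.57, and HLA-B was higher by 1.19, each past the threshold in limma, the first pair and LEF1 in the direction of the knockouts and HLA-B against it.

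**Figure D2:**
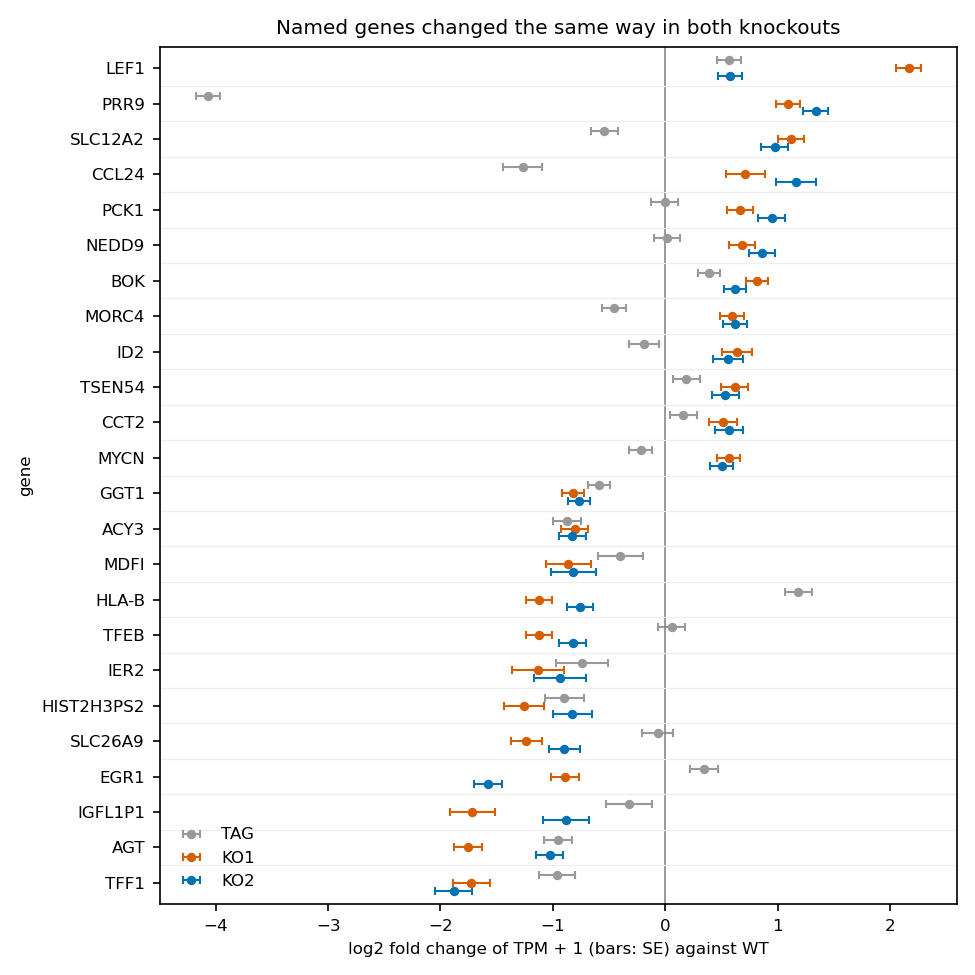
Log2 fold change of TPM + 1 against WT (horizontal axis) of the 24 genes named as changed the same way in both knockouts (vertical axis), with points for TAG (grey), KO1 (orange) and KO2 (blue) and bars for the SE (3 libraries per group). PRR9 lies at 1.09 and 1.34 in the knockouts and at -4.07 in TAG.

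Each knockout alone changed many more genes than the pair shared. Of 17197 genes, 802 changed in KO1, 553 higher and 249 lower, and 881 in KO2, 133 higher and 748 lower. Common to both were 101 genes, 21 higher and 80 lower, and 53 of these (11 higher and 42 lower) also passed with the same sign against TAG. The directions depended on scaling. As deposited, the median of all genes was 0.11 in KO1 and -0.09 in KO2 on the log2 scale, and quantile normalization brought both to 0.02. It gave 874 higher and 1030 lower genes in KO1, 560 and 788 in KO2, and 101 and 217 in common. No named gene changed sign under it. In KO1 the membrane dipeptidase DPEP1 fell from 49.3 ± 5.14 to 4.57 ± 0.48 TPM (-3.17 ± 0.12, limma adjusted p = 2.2e-07). OAF fell by 1.82 and PDX1, an endodermal transcription factor, by 1.36. The actin crosslinker FLNA rose from 17.9 to 51.0 TPM (1.46 ± 0.20), SMOC2 by 1.34, NXN by 1.29 and SCRN1 by 1.28. The readthrough model C7orf55-LUC7L2 rose by 3.22 ± 0.82, with 5 libraries of the table listed at 0. In KO2 the acetyl-CoA synthetase ACSS1 rose from 2.14 to 18.6 TPM (2.64 ± 0.12, limma adjusted p = 1.2e-06). The water channel AQP1 rose from 24.5 ± 15.6 to 83.7 ± 36.9 TPM, and C12orf75, LRP4 and PAM rose by 1.37, 1.34 and 1.21. The stress cytokine GDF15 fell from 27.8 to 6.29 TPM (-1.97 ± 0.12), the siderophore-binding protein LCN2 from 11.4 to 2.27, the protease inhibitor SLPI from 30.0 to 8.63, the decoy receptor IL1R2 from 66.1 to 21.1, and CASC19 by 1.87. Leaving out any library of KO1 or WT lowered the KO1 count to between 367, without WT replicate 1, and 453, without WT replicate 2. The KO2 count was 421, 437, 497 and 520 without WT replicates 1 and 2 and KO2 replicates 1 and 2, and the common count 42, 48, 51, 56 and 54 without WT replicates 1 and 2, KO1 replicates 1 and 2 and KO2 replicate 1.

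Against WT, the mean of both knockouts gave 11 of 21 testable lists past the threshold in camera. Stress genes of the unfolded protein and amino acid responses were lower, with 5 of 24 lower and none higher (10 adjusted over the list alone). The mTORC1 inhibitor DDIT4 fell in KO2 by 1.57 ± 0.10 from 44.6 TPM and stood at -0.34 in KO1 without passing. PHGDH and ASNS, enzymes of serine and asparagine synthesis, fell in KO2 by 1.23 and 1.27, while CEBPB fell in KO1 by 0.55 and in KO2 by 0.47. NF-kB and inflammatory genes were lower in 4 of 14 cases (6 adjusted over the list alone), with the chemokine CXCL2 lower in KO1 by 0.90 and in KO2 by 0.80 and the cytokine CSF2 lower in KO2 by 2.26 ± 0.17. Immediate early genes were lower in 6 of 28 cases and higher in 1 (8 and 1 adjusted over the list alone), JUNB by 0.72 and 0.97 and SPRY2, a feedback inhibitor of growth factor signalling, by 0.55 and 0.51, whereas FOS at 172 TPM did not pass (-0.32 and -0.26). Colon epithelium genes were lower in 5 of 23 cases and higher in 1 (6 and 3 adjusted over the list alone). Among them FABP1 fell in KO1 by 2.38, the trefoil peptide TFF3 fell in KO2 from 149 to 66.3 TPM (limma adjusted p = 8.9e-05), and AGR2, a disulfide isomerase of secretory cells, rose in KO2 by 1.17. Interferon response genes were lower in 3 of 30 cases (4 adjusted over the list alone), EPSTI1 by 1.02 and IFI27 by 1.07 in KO2. For p53 targets 2 of 22 were lower (3 adjusted over the list alone), GDF15 and PHLDA3. The tests gave adjusted p = 1.4e-06, 8.5e-05, 8.5e-05, 0.0088, 0.0093 and 0.049 for these 6 lists, and each call was lost at adjusted p = 0.78, 0.44, 0.78, 0.78, 0.78 and 0.78 with an estimated correlation. The p53 call was also lost with quantile normalization (adjusted p = 0.070). The same lists were read in each knockout. In KO1, 1 of the stress genes was lower, 2 NF-kB and inflammatory genes were higher and 1 lower, 4 immediate early genes were higher and 4 lower, 1 interferon response gene was higher and 2 p53 targets were higher. Adjusted over the list alone these counts were 1 lower, 2 and 3, 6 and 8, 2 and 2, and 2 higher, and none of these 5 lists passed in KO1 (adjusted p = 0.20, 0.38, 0.072, 0.86 and 0.88). In KO2, 11, 6, 10, 7 and 6 of their members were lower (14, 10, 12, 13 and 10 adjusted over the list alone), and each list passed, at adjusted p = 2.7e-08, 7.2e-08, 1.1e-07, 2.5e-05 and 0.0021, and at adjusted p = 0.44, 0.072, 0.46, 0.46 and 0.46 with an estimated correlation. The colon epithelium list passed in KO1, with 6 lower and 1 higher (9 and 2 adjusted over the list alone, adjusted p = 3.7e-06, and adjusted p = 0.99 with an estimated correlation). It did not pass in KO2, with 4 lower and 3 higher (5 and 4 adjusted over the list alone, adjusted p = 0.77). Set directly against each other, KO1 and KO2 differed in all 6 lists, at adjusted p between 3.8e-06 and 0.015, and between adjusted p = 0.62 and 0.86 with an estimated correlation.

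Higher as lists in the mean of the knockouts were proliferation genes (1 of 34 members higher, CCNE2, also 1 adjusted over the list alone) and cholesterol synthesis genes (1 of 24, SC5D, and 4 adjusted over the list alone). The list test also passed upward for heat shock genes (median 0.17) and replication-dependent histones (median 0.09), although 0 of 13 and 0 of 50 members passed by limma, also adjusted over the list alone. Ribosomal protein genes were lower as a list, with 0 of 61 members past the threshold and a median of -0.08. These tests gave adjusted p = 0.0088, 0.018, 0.012, 0.048 and 0.018, and adjusted p = 0.78, 0.78, 0.78, 0.81 and 0.80 with an estimated correlation. The cyclin CCNE2 rose in KO1 by 1.24 ± 0.19, the sterol enzyme SC5D by 0.80, and the chaperone HSPH1 rose in KO2 by 0.53. The proliferation list passed in KO1 and not in KO2 (adjusted p = 0.018 and 0.098), as did the ribosomal list (adjusted p = 0.0083 and 0.44), and the heat shock list passed in KO2 and not in KO1 (adjusted p = 1.5e-05 and 0.98), where the calls were lost at adjusted p = 0.99, 0.99 and 0.44 with an estimated correlation. In the direct test of KO1 against KO2 the proliferation and ribosomal lists did not pass (adjusted p = 0.37 and 0.11), so a difference between the knockouts was not shown for them. The heat shock list passed there (adjusted p = 4.1e-04, and adjusted p = 0.68 with an estimated correlation). The cholesterol and histone lists passed in neither (adjusted p = 0.072 and 0.098 for cholesterol synthesis, 0.072 and 0.44 for histones, in KO1 and KO2). Histones had a median of 0.24 in KO1, with 40 of 50 above 0. In KO2 their median was -0.06, with 15 of 50 above 0, while the test pointed up, and the median was 0.01 after quantile normalization. Summed over the list, histone transcripts held 12405 ± 1098 TPM in WT, 14010 ± 1196 in KO1 and 12032 ± 1233 in KO2 (SD, n = 3). The other lists did not pass in the mean. WNT targets had 2 of 17 higher, LEF1 and CD44 (3 adjusted over the list alone, list adjusted p = 0.054, and 0.046 without KO2 replicate 2). The WNT list passed as higher in KO2, with 2 of 17 higher (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.0056, and adjusted p = 0.84 with an estimated correlation), and not in KO1, with 1 higher (4 adjusted over the list alone, adjusted p = 0.71), and the direct test between them gave adjusted p = 0.18. Mesenchymal genes had 1 of 13 higher, CD44 (2 higher and 1 lower adjusted over the list alone, list adjusted p = 0.81), epithelial adhesion genes 1 of 26 lower, LAMB3 (2 higher and 3 lower, list adjusted p = 0.77), and hypoxia and glycolysis genes 1 of 27 lower, VEGFA (1 higher and 3 lower, list adjusted p = 0.30). No member passed among 13 miRNA pathway, 31 transposon restriction, 20 KRAB zinc finger and 13 mitochondrially encoded genes or the 4 markers of other cell types (adjusted p = 0.090, 0.65, 0.15, 0.086 and 0.65 for the lists), and adjusted over the list alone 1 KRAB zinc finger gene was higher. The mean of the knockouts hides opposite calls for these markers. Alongside the list changes given above for each knockout, they were lower as a list in KO1 (3 adjusted over the list alone, adjusted p = 2.0e-04, and adjusted p = 0.052 with an estimated correlation) and higher in KO2 (3 adjusted over the list alone, adjusted p = 0.0013, and adjusted p = 0.072 with an estimated correlation). LYZ rose in KO2 by 0.66 and CD68, a macrophage lysosomal protein, fell in KO1 by 1.01.

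The fold changes of KO1 and KO2 correlated across genes, which are not independent replicates, at r = 0.39. Simulated unchanged groups with a common simulated control gave 0.50, which sharing a control of equal size gives by itself. Their covariance was 0.0464 against 0.0258 in the simulation, a difference of 0.0207. The difference was 0.0343 for TAG and KO1 and -0.000769 for TAG and KO2. Independent lists would share 4.28 higher and 10.8 lower genes between the knockouts, where 21 and 80 were found. A further 61 went opposite ways, so overlap alone shows no shared response. TAG and KO1 shared 118 higher and 101 lower, where 19.7 and 7.33 would be. In 20 simulated draws no comparison gave a call, so they say nothing about this overlap. WT libraries are too few to split, so part of each excess may come from shared controls. KO1 and KO2 differed from each other in 3083 genes, 2745 higher and 338 lower in KO1, a split of 1429 and 1368 with quantile normalization. The count was 1700 without KO2 replicate 2 and 2003, 1844 and 1885 without KO1 replicates 1, 2 and 3.

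Knockdown with each of the 3 hairpins was compared with CTRL. LCN2 fell from 135 ± 11.4 TPM in CTRL to 41.9, 33.7 and 46.5 TPM in SH1, SH2 and SH3 (-1.67, -1.97 and -1.51, each ± 0.11). HLA-B fell from 41.2 ± 2.02 TPM by 1.14, 1.23 and 0.70 on the log2 scale. MCTP1 fell by 0.88, 1.01 and 0.97, the trypsinogen PRSS2 by 0.52, 0.66 and 0.62, and FGF19, an enterohepatic growth factor, was lower by at least 0.43 in each. PCK1 rose from 9.30 ± 0.64 to 18.2, 20.7 and 31.9 TPM (0.90, 1.07 and 1.68, each ± 0.10). The aldo-keto reductases AKR1C2 and AKR1C1, DGCR6 and the fatty acid desaturase SCD were higher with every hairpin, SCD at 140 TPM in CTRL and 204, 202 and 201 TPM in SH1, SH2 and SH3.

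Replication-dependent histone genes, which make most histone protein during S phase, rose together. Of 50 tested, 24 rose with SH1, 45 with SH2, 31 with SH3 and 43 in the mean of the hairpins, and none fell. Adjusted over the list alone the counts were 44, 47, 45 and 48. HIST1H1B rose from 377 ± 18.4 to 587, 585 and 564 TPM, HIST1H1D from 244 to 365, 361 and 343 TPM, and HIST1H3C by 0.68 ± 0.05 in the mean from 117 TPM. HIST1H2AB, HIST1H3J, HIST1H3I and HIST1H2BG rose with every hairpin, while HIST1H4C at 442 TPM did not pass in the mean (0.16 ± 0.05, limma adjusted p = 0.15). Summed over the list, histone transcripts held 7755 ± 171 TPM in CTRL, 10105 ± 278 in SH1, 11237 ± 321 in SH2 and 10173 ± 17.4 in SH3 (SD, n = 3). The camera test of the mean gave adjusted p = 6.9e-63 and held (adjusted p = 0.0022 with an estimated correlation). The direction held with quantile normalization, at a median of 0.39 against 0.46 as deposited.

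**Figure D3:**
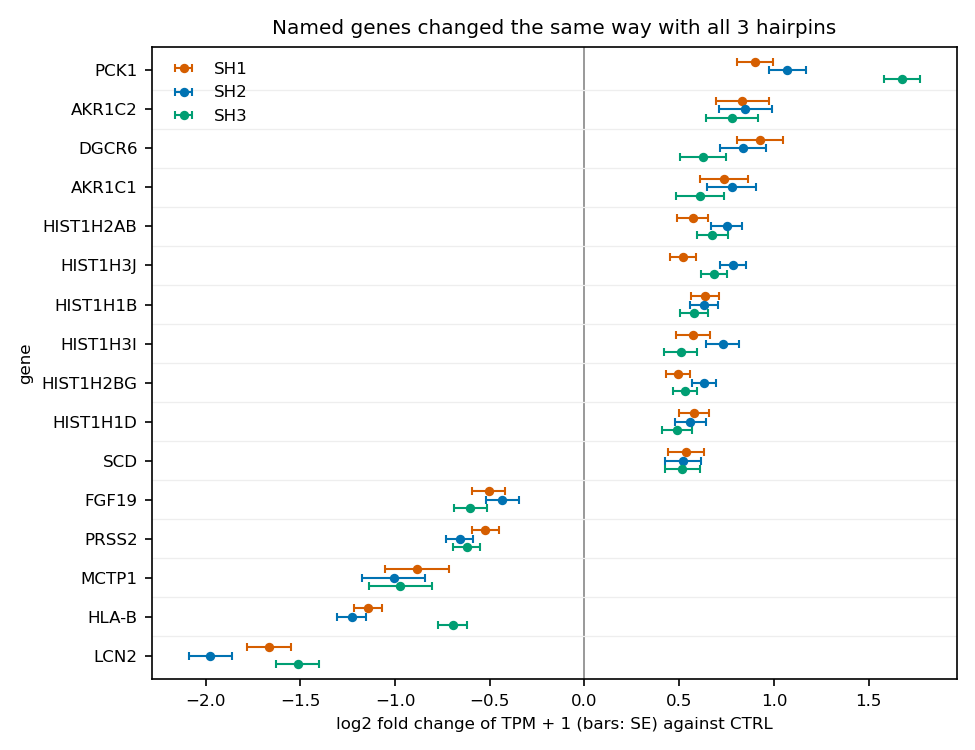
Log2 fold change of TPM + 1 against CTRL (horizontal axis) of 16 genes named as changed the same way with all 3 hairpins (vertical axis), with points for SH1 (orange), SH2 (blue) and SH3 (green) and bars for the SE (3 libraries per group). PCK1 lies between 0.90 and 1.68 and LCN2 between -1.97 and -1.51.

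Other genes moved with single hairpins. With SH1, GYS1 and TRMT11 rose by 0.77 and 0.76, TNFRSF19, a WNT-regulated receptor, fell from 11.8 to 5.93 TPM, the interferon-induced IFI6 from 24.1 to 12.6 and the calcium-binding S100A4 from 164 to 107 TPM. With SH2, IL1R2 rose by 0.79 to 21.4 TPM, ZNF664 rose by 1.68 ± 0.31 in overlapping models, AMACR, a racemase of fatty acid breakdown, fell by 0.68, PRSS1 by 0.67 and IFI6 by 0.92. With SH3, FRMD4B, ORMDL2 and BCAS1 rose by 0.96, 0.85 and 0.89, ZNF664 and TMEM189, both overlapping models, rose by 1.80 and 1.68, and the stress pseudokinase TRIB3 fell from 84.9 to 38.1 TPM (-1.13 ± 0.09). The growth factor AREG fell from 89.1 to 42.1 TPM with SH3, ITPKA from 26.9 to 12.7 and MMP24-AS1 by 1.61. Of 14283 genes, 88 changed with SH1 (60 higher, 28 lower), 126 with SH2 (104 and 22), 237 with SH3 (171 and 66) and 46 with all of them (36 and 10). Quantile normalization gave splits of 67 and 47, 82 and 41, 171 and 154, and 31 and 16, and it moved the median of all genes by less than 0.1. For the pairs of hairpins the covariance exceeded the simulated one by 0.0235, 0.00957 and 0.0180 (SH1 with SH2, SH1 with SH3, SH2 with SH3). SH1 and SH2 shared 45 higher and 13 lower genes, where independent lists would share 0.437 and 0.0431, and part of the excess may come from the shared CTRL libraries. Leaving out CTRL replicate 3 took the counts to 15, 69, 60 and 9 for SH1, SH2, SH3 and all hairpins. Leaving out CTRL replicates 1 or 2 gave 37 and 39 for SH1, 75 and 83 for SH2, 94 and 106 for SH3 and 18 and 20 for all, and several single hairpin libraries moved the counts as far.

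Of 20 testable lists, 6 passed for the mean of the hairpins, the histones among them. Colon epithelium genes rose in 3 of 20 cases (5 higher and 1 lower adjusted over the list alone), with AGR2 up by 0.45 in the mean from 81.5 TPM, PHGR1 by 0.38 and the intestinal antigen GPA33 by 1.11 ± 0.22. Transposon restriction genes were higher as a list with 0 of 29 past the threshold (1 adjusted over the list alone). Mesenchymal genes fell in 2 of 8 cases, S100A4 by 0.39 and the integrin ITGA5 by 0.63 (2 adjusted over the list alone). Stress genes fell in 1 of 24 cases, TRIB3 by 0.39 in the mean (1 higher and 2 lower adjusted over the list alone), and in 7 cases with SH3, where HERPUD1 fell by 0.79, PPP1R15A by 0.75, DDIT4 by 0.70 and PDIA4 rose by 0.40. Ribosomal protein genes were lower as a list with 0 of 61 past the threshold and a median of -0.01. The tests gave adjusted p = 0.0069, 0.014, 0.0071, 0.0020 and 0.014, and adjusted p = 0.58, 0.63, 0.31, 0.63 and 0.58 with an estimated correlation. Among the lists that did not pass, IFI6 fell by 0.70 in the interferon list of 30 (adjusted p = 0.22), LCN2 by 1.72 and IL23A by 0.58 in the NF-kB and inflammatory list of 13 (adjusted p = 0.19, with a median of 0.00 and a mean of -0.08). TNFRSF19 fell by 0.62 and EPHB2 rose by 0.47 among 17 WNT targets (adjusted p = 0.56), and BTG2 rose by 0.59 among 21 p53 targets (adjusted p = 0.52). For WNT and p53 targets, hypoxia and glycolysis genes and KRAB zinc finger genes the median was above 0 while the test pointed down. Adjusted over the list alone these counts were the same. No gene passed in the mean among 34 proliferation, 24 cholesterol synthesis, 26 epithelial adhesion, 27 hypoxia and glycolysis, 12 heat shock, 22 immediate early, 19 KRAB zinc finger, 13 miRNA pathway and 13 mitochondrially encoded genes (adjusted p = 0.52, 0.29, 0.14, 0.46, 0.31, 0.52, 0.22, 0.22 and 0.16). Adjusted over the list alone, 1 proliferation gene and 3 epithelial adhesion genes were higher. With single hairpins, epithelial adhesion, immediate early and mitochondrially encoded genes passed as higher lists with SH1 (adjusted p = 0.048, 0.047 and 8.3e-04), piRNA pathway genes as lower with SH2 (adjusted p = 0.039), and cholesterol synthesis genes as higher and NF-kB and inflammatory genes as lower with SH3 (adjusted p = 0.0075 for each). These calls were lost at adjusted p = 0.79, 0.79, 0.79, 0.58, 0.31 and 0.31 with an estimated correlation. The piRNA list holds PIWIL1, listed at 0 in SH2 replicate 3, so its call is not independent of the knockdown. With SH3 alone, 5 of 34 proliferation genes rose, among them the replication helicase subunits MCM5 (0.80), MCM6 (0.67) and MCM3 (0.66), at a list adjusted p = 0.0087 that was lost (adjusted p = 0.65 with an estimated correlation). Fewer than 3 markers of other cell types were tested, and neither CD68 at 32.2 TPM nor LYZ at 581 TPM passed.

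Knockout and knockdown were compared over the 14069 genes tested in both tables. Only PCK1 was higher in every comparison of both experiments, only HLA-B was lower in every comparison, and TESC was higher in both knockouts and lower with all hairpins. Chance would give 0.0409, 0.0381 and 0.00910 such genes, with Fisher's exact p = 0.0402, 0.0375 and 0.00906 and adjusted p of 0.0536, 0.0536 and 0.0363 within the 4 directions. No gene was lower in both knockouts and higher with all hairpins, where 0.171 would be by chance. In the mean contrasts 3 genes were higher in both (PCK1, AGR2 and BBS2) and 5 were lower in both (HLA-B, LCN2, SLPI, PRSS1 and RAD9B), where chance would give 0.726 and 0.532, with Fisher's exact p = 0.0362 and 1.7e-04. A further 7 were lower in the knockouts and higher in the hairpin libraries, among them IL1R2, AKR1B10 and ID1, where chance would give 2.22 (Fisher's exact p = 0.00698). Across genes, which are not independent, the mean changes of the 2 experiments correlated at r = -0.022 (Spearman 0.0084). TESC, BBS2, RAD9B, IL1R2 in this pairing and ID1 were named after their values were seen.

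Transposon families were compared to see whether loss of PIWIL1 was followed by more transposon RNA. In both knockouts 8 of 1023 families were lower than WT and none was higher, by edgeR. HERVIP10F-int, the internal part of an endogenous retrovirus, fell by 0.50 ± 0.04 in KO1 and 0.51 ± 0.04 in KO2 (adjusted p = 5.5e-06 and 2.4e-06). HERV9NC-int fell by 0.36 and 0.45, each ± 0.04, HERVK13-int by 0.43 and 0.60, and LTR10E by 0.38 and 0.41. ERV3-16A3_I-int, MER57A1, HERV9N-int and HERV9-int fell by 0.19 to 0.30. All 8 also passed as lower against TAG. The young LINE-1 family L1HS, which can still move in the human genome, stood at -0.02 ± 0.05 in the mean of the knockouts (edgeR adjusted p = 0.88). The HERV-9 and LTR12 list was lower in KO1, KO2 and their mean, with 3 of 9 members lower in each (8, 6 and 7 adjusted over the list alone) and a median of -0.22 in the mean. Its adjusted p of 9.5e-11 in the mean held (adjusted p = 0.018 with an estimated correlation), and in KO1 alone it gave adjusted p = 0.073 with an estimated correlation.

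The other fixed transposon lists did not change in the mean of the knockouts. None of 4 young LINE-1, 5 young Alu, 6 SVA, 4 HERV-K (HML-2), 5 HERV-H and 14 primate-specific LTR families passed, and adjusted over the list alone 3 SVA and 3 primate-specific LTR families were lower (list adjusted p = 0.90, 0.90, 0.057, 0.90, 0.65 and 0.38). The SVA list passed without KO2 replicate 2 (adjusted p = 0.020), and for young Alu and HERV-K (HML-2) the median was below 0 while the mean and the test pointed up. The L1 family group was slightly higher, with 2 of 132 members higher and a median of 0.06 (adjusted p = 3.0e-09, and adjusted p = 0.46 with an estimated correlation), as were class LINE and the TcMar-Tc2 families (adjusted p = 3.2e-08 and 0.022, and 0.36 for both as adjusted p with an estimated correlation). Lower were class LTR (20 of 561 lower, 4 higher), ERV1 (12 of 292 lower, 4 higher) and ERVK (3 of 41 lower), with adjusted p = 4.1e-05, 0.022 and 0.020, and adjusted p = 0.21, 0.26 and 0.16 with an estimated correlation. Single families moved further in single lines. HERV1_I-int rose in TAG by 1.17 ± 0.05, LTR70 and LTR1B1 rose in KO2 by 0.87 and 0.79, AluYi6 rose in KO2 by 0.57, MER4-int fell in KO1 by 0.80 ± 0.08 and the DNA transposon Charlie12 fell in TAG by 0.83 and in KO1 by 0.86. In TAG 81 families changed (41 higher, 40 lower), in KO1 36 (13 and 23) and in KO2 28 (11 and 17). These counts and their split depended on the scaling and the tool. Total counts gave 104 in TAG (87 higher, 17 lower), 81 in KO1 (66 and 15) and 22 in KO2 (4 and 18), DESeq2 gave 92 (49 and 43), 70 (37 and 33) and 31 (12 and 19), and DESeq2 size factors within edgeR gave 52 in KO1 (27 and 25). With only the libraries compared TAG had 145 (57 and 88) and KO1 18 (3 and 15). In TAG, L1 families rose in 24 of 132 cases and fell in 1, and Alu families fell in 7 of 51 (adjusted p = 1.8e-12 and 7.4e-11, and adjusted p = 0.74 and 0.76 with an estimated correlation). With total counts in place of TMM scaling only 4 of the 8 common families passed, and the common count was 4 without KO1 replicate 2, 5 without WT replicate 3 and 13 without KO2 replicate 3.

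**Figure D4:**
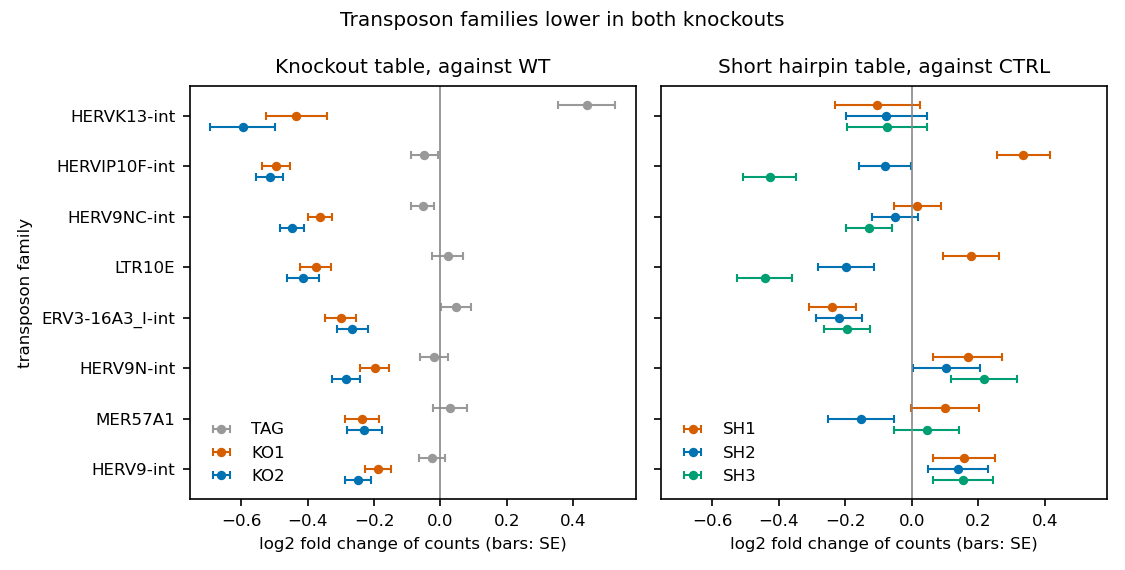
Log2 fold change of repeat counts (horizontal axes) of the 8 transposon families lower in both knockouts (vertical axis), against WT for TAG, KO1 and KO2 (left) and against CTRL for SH1, SH2 and SH3 (right), with bars for the SE (3 libraries per group). HERVIP10F-int lies at -0.50 and -0.51 in the knockouts, and at 0.34, -0.08 and -0.43 with the hairpins.

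With the hairpins no transposon family changed the same way in all comparisons by edgeR, where 25 of 990 were at an unadjusted p under 0.05 with 1 sign and DESeq2 also gave 0. SH1 changed 0 families by edgeR (97 at an unadjusted p under 0.05, 14 by DESeq2), SH2 changed 42 (6 higher and 36 lower) and SH3 changed 4, all lower. With total counts in place of TMM scaling the directions turned, to 352 families with SH2 (349 higher, 3 lower) and 3 with SH3, all higher. DESeq2 gave 52 (9 and 43) and 12, all lower, and with only the libraries compared SH2 had 16 (1 and 15) and SH3 20 (2 and 18). On the TMM scale, with SH2 the LINE-1 families L1PA3 and L1PA6 rose by 0.30 and 0.31, LTR1B1 rose by 1.13, LTR15 fell by 0.65 and MER11B fell by 0.77 ± 0.18. With SH3, LTR48, LTR10E, HERVIP10F-int and Tigger16b fell by 0.46, 0.44, 0.43 and 0.38. MER11B alone took 43.1% ± 1.54 of the repeat counts in CTRL and 30.7% ± 7.78 in SH2 (SD, n = 3), and 5.21% to 10.3% in libraries of the knockout table. In the mean of the hairpins, young LINE-1 families were higher as a list with 0 of 4 past the threshold (2 adjusted over the list alone, median 0.13, adjusted p = 0.036, and adjusted p = 0.46 with an estimated correlation), and this call ended without SH2 replicate 3 (adjusted p = 0.074). Alu and L1 families were higher as groups (adjusted p = 0.036 and 0.028), calls that also ended without that library (adjusted p = 0.15 and 0.074), although the hairpins did not move these groups alike, with Alu medians of 0.27, -0.03 and -0.11 and L1 medians of -0.05, 0.08 and 0.05 for SH1, SH2 and SH3, while class DNA (8 of 220 lower), hAT-Charlie (3 of 73 lower) and TcMar-Tigger (3 of 61 lower) were lower (adjusted p = 5.9e-06, 0.0041 and 2.3e-04). These 5 calls were lost at adjusted p = 0.89, 0.89, 0.46, 0.46 and 0.46 with an estimated correlation. Young Alu, SVA, HERV-K (HML-2), HERV-H, HERV-9 and LTR12, and primate-specific LTRs did not pass (adjusted p = 0.87, 0.90, 0.78, 0.48, 0.20 and 0.55), with no member past the threshold by edgeR or when adjusted over the list alone. For SVA and HERV-K (HML-2) the median was below 0 while the test pointed up. The SH2 count of 42 moved to 9, 12, 14, 10, 73 and 98 without SH2 replicate 3, SH2 replicate 2, CTRL replicates 1, 3 and 2 and SH2 replicate 1, and the SH3 count of 4 moved to 16 without CTRL replicate 2 and to 0 without any other library.

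Small RNAs were examined for piRNA-sized reads, which are longer than miRNAs. Reads of 24 to 32 nt made up 41.2%, 67.8%, 27.1% and 11.2% of the 4 IP libraries (36.8% ± 24.01, SD, n = 4), 49.4% of the background library (95% exact interval 49.3% to 49.5%) and 45.5%, 8.69% and 27.3% of the sRNA libraries (27.2% ± 18.4, n = 3). The difference of 9.65 points between IP and sRNA was within the spread (exact two-sided permutation p = 0.686, smallest possible 0.0571), and only 1 IP library exceeded the background. Of these lengths 24 nt, next to the miRNA lengths, was the most frequent in 7 of 8 libraries (28 nt in IP library 1), and it alone held 9.07%, 23.8%, 8.69% and 6.08% of reads in IP, 23.1% in the background and 30.7%, 3.69% and 21.7% in sRNA. Reads of 25 nt or more, a range chosen after these values were seen, made up 32.3%, 44.0%, 18.5% and 5.12% of the IP libraries, 26.3% of the background and 14.9%, 5.0% and 5.57% of the sRNA libraries. Their mean was 24.96% ± 16.8 in IP (n = 4) and 8.49% ± 5.55 in sRNA (n = 3), a difference of 16.5 points (exact permutation p = 0.171). The most frequent read length was 23, 24, 20 and 23 nt in the IP libraries, 23 nt in the background and 24, 23 and 23 nt in the sRNA libraries. Among lengths of 25 nt or more, a peak at 28 nt held 9.71%, 11.1% and 5.13% of reads in IP libraries 1 to 3, 9.84% in the background and 1.11% in sRNA library 3, and there was none at 28 nt in IP library 4 or sRNA libraries 1 and 2. Another at 26 nt held 6.83% and 3.92% in IP libraries 1 and 3 and 4.04% in the background. For 26 to 31 nt, IP held 19.8%, sRNA 5.78% and the background 21.8% of reads (exact permutation p = 0.171 for IP against sRNA). IP and the sRNA libraries were deposited in separate tables, and depth ran from 291234 to 8639319 reads in IP, 585860 in the background and 4949892 to 18956883 in sRNA. The label of the background library gives the same tagged genotype as the IP libraries and not how it differs from them, so it is not known to lack tagged PIWIL1. With 1 background library its comparison with IP has no replicate check, and the difference between IP and sRNA was -0.667 points without IP library 2 and 0.409 without sRNA library 2.

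**Figure D5:**
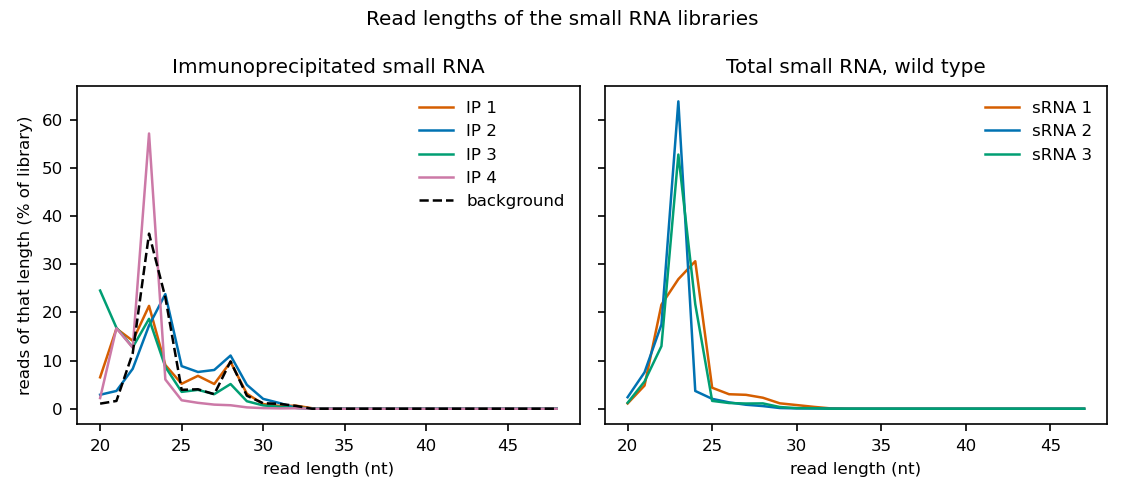
Share of reads (percent of the library's deposited reads, which start at 20 nt, vertical axes) at each read length in nt (horizontal axes), for the 4 IP libraries and the background library (left) and the 3 sRNA libraries (right), with 1 line per library. The background line peaks at 23 nt and, lower, at 26 nt and 28 nt, where it holds 4.04% and 9.84% of its reads.

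In the authors' annotation of the immunoprecipitated reads, miRNA was the largest class in the mean, with 73.4% ± 17.3 of reads in IP (SD, n = 4) and 82.3% in the background. Fragments of mRNA made up 6.57% ± 4.47 against 3.99%, introns 3.56% ± 2.29 against 2.19%, snoRNA 1.59% ± 1.33 against 1.65%, and unassigned or other reads 12.6% ± 7.78 against 8.24%. Reads from repeats, the usual targets of piRNAs, made up 2.21% ± 1.75 against 1.62%, above the background in 2 of 4 IP libraries. Reads classed as tRNA made up 0.117% ± 0.0617 against 0.0243%, above the background in 4 of 4 libraries. Mitochondrial tRNA, a separate class, held 2.85%, 2.23%, 3.28% and 1.11% against 1.82%. With 1 background library, none of these differences was tested.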

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

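Of the tests in this part, the comparison of covariances for KO1 and KO2 separately, those of scaling and of S phase for the histones, and those of count normalization, of reads from the PIWIL1 transcript and of a lower level of PIWIL1 mRNA for the transposon families, were chosen only after the results were seen.

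KO1 and KO2 differed from each other in 3083 genes and 71 transposon families, by the test of the difference itself (limma and edgeR). DPEP1, picked after its values were seen as the gene with the smallest adjusted p there, had a log2 difference of -3.75 ± 0.12 between KO1 and KO2 (SE, limma adjusted p = 3.2e-08). Among the hairpins, SH1 and SH2 differed in 2 genes and 11 transposon families, SH1 and SH3 in 166 genes and 36 families, and SH2 and SH3 in 9 genes and 1 family. HERVIP10F-int, which was lower in both knockouts, was higher with SH1 than with SH3 by 0.76 ± 0.08 (SE, edgeR adjusted p = 1.5e-05). The simple repeat (CATTC)n, outside the transposon comparisons, had a count of 842 in SH2 replicate 3, where the CTRL libraries held 20 to 94, SH2 replicate 2 held 213 and SH3 replicate 1 held 245. Among the 4 IP libraries, 0 of 13 tests by Dixon's criterion set a library apart, at a highest ratio of 0.741.

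KO1 and KO2 differed from each other in more genes than either differed from WT (802 and 881). Scaling was not the whole source, since 2797 genes differed after quantile normalization, where KO1 and WT differed in 1904, although the excess of genes higher in KO1 (2745 against 338) became 1429 against 1368. No single library accounted for it, since leaving out any 1 gave at least 1700 genes, the value without KO2 replicate 2, with 2003, 1844 and 1885 without KO1 replicates 1, 2 and 3. Were loss of PIWIL1 the main difference of KO1 from WT, KO1 would share more with KO2 than with TAG. This assumes that PIWIL1 works in TAG and is lost in the knockouts, and protein was not measured here. The covariance beyond the simulated one was 0.0207 for KO1 and KO2 and 0.0343 for TAG and KO1 (a difference, before that subtraction, between -0.0160 and -0.0108 without any 1 library). TAG and KO2 gave -0.000769 (a difference between 0.0191 and 0.0230). A covariance also grows with the size of the changes in each line. Only under that assumption do these values argue against loss of PIWIL1 as the main difference, for KO1 and not for KO2. Differences between cell clones that have nothing to do with PIWIL1 may account for much of the change in each line, but how the lines were derived is not given in the sources used here, and this was not tested.

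Replication-dependent histone transcripts were higher with all 3 hairpins. Scaling and exchange of reads between near-identical histone copies were argued against, by a median of 0.39 after quantile normalization against 0.46 as deposited, and by a lowest summed histone level of 9847 TPM in a hairpin library against a highest of 7951 TPM in CTRL. Better recovery of short genes would raise other protein-coding genes with a span of 2000 bp or less, whose median was 0.0485 over 185 genes (6 higher, 3 lower). More cells in S phase would raise replication genes, and this explanation stays open. The proliferation list had a median of 0.0314 in the mean of the hairpins. Its upper bound of 0.0953 came from the spread across genes, which are not independent. With SH3, 5 of its 34 genes rose, among them the replication genes MCM5, MCM6 and MCM3, and the list passed as higher. A response of the cells to knockdown of PIWIL1 stays open as a hypothesis, as does anything else that set the single CTRL group apart, such as its handling, which these libraries do not separate from the hairpins.

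8 transposon families were lower in both knockouts. Count normalization was argued against as the whole source for HERVIP10F-int, HERVK13-int, LTR10E and HERV9NC-int, which stayed at -0.27 or lower in both knockouts when total counts replaced TMM factors, but stays open for the 4 that lost a call in KO1, from -0.19 ± 0.04 to -0.0967 ± 0.0588 for HERV9-int, from -0.20 ± 0.04 to -0.10 ± 0.06 for HERV9N-int, from -0.24 ± 0.05 to -0.15 ± 0.07 for MER57A1 (also lost in KO2, at -0.26 ± 0.07) and from -0.30 ± 0.05 to -0.21 ± 0.06 for ERV3-16A3_I-int (SE), since total counts moved the folds in KO1 by a mean of 0.09 and widened the mean SE from 0.05 to 0.07, while 0 of the 8 lost a call with DESeq2 or with its size factors. Reads from the PIWIL1 transcript and a lower level of PIWIL1 mRNA were argued against only weakly for the families as a set. Their median was -0.34 in the knockouts, but they were chosen as lower there, so that value may be overstated. An SE across the 8 families treats them as independent and leaves out the spread between libraries. With that SE the median was -0.0556 ± 0.0593 in the mean of the hairpins, where PIWIL1 mRNA was further below its control. In that mean 0 of the 8 were lower past the threshold by edgeR (2 at an unadjusted p under 0.05). DESeq2 was run, but its values for this mean were not kept for all 8. However, HERVIP10F-int and LTR10E were lower with SH3 alone. Both explanations stay open for ERV3-16A3_I-int, at -0.24, -0.22 and -0.20 with SH1, SH2 and SH3. It stood at -0.22 ± 0.06 in their mean (SE, edgeR adjusted p = 0.054) against -0.28 ± 0.04 in the knockouts. Loss of PIWIL1 protein may also lower these families, directly or through the state of the cells, but protein was not measured here and the direction is opposite to the loss of silencing that transposon targeting by PIWIL1 would lead to.

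Other divisions of the libraries were tried for each count. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real count of genes, with the highest count among the other splits, was 1120 and 4 for TAG, 802 and 3 for KO1, 881 and 2 for KO2, 3083 and 2 for KO1 against KO2, 88 and 3 for SH1, 126 and 3 for SH2, and 237 and 2 for SH3, so 1 of 10 splits, the real one, reached it each time. For transposon families the pairs were 81 and 0, 36 and 0, 28 and 1, 71 and 0, 0 and 1, 42 and 22, and 4 and 0 in the same order, again with 1 split each except SH1, whose count of 0 was reached by 10 of 10. Among 100 regroupings of the 9 or 12 libraries of a table, few reached the genes common to both knockouts (4 of 100 reached 101) or their 8 common families (2 of 100, highest other 8). Few also reached the number of gene lists in the knockouts (1 of 100 reached 11, highest other 10) or the genes common to the hairpins (1 of 100 reached 46, highest other 2). A regrouping puts libraries of different lines or hairpins into 1 group, which can widen the spread and lower the calls. These shares therefore do not exclude chance. The 3 other regroupings that reached 101 gave 382, 389 and 395 genes, which points to a structure of the samples. Each set all 3 libraries of 1 knockout (KO2 in 2 of them, KO1 in 1) against mixtures of WT and the other knockout, so they follow the difference between KO1 and KO2. More regroupings reached the number of transposon lists in the knockouts (46 of 100 reached 7, highest other 18) and of gene lists in the hairpin table (8 of 100 reached 6, highest other 8). The same held for transposon lists there (33 of 100 reached 6, highest other 13) and common transposon families there, where the real count was 0 (100 of 100).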

How the results depend on the processing

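The PIWIL1 tests and the list tests without SH2 replicate 3 or KO2 replicate 2, robust empirical Bayes moderation, the repeat fit without MER11B and the small RNA range of 25 nt or more were chosen only after the results were seen, and the other settings, all of which were run, were planned. Of 451 named single results 268 passed. Of 3856 alternative values of those that passed, 726 lost the call and 0 changed sign, and of 4785 values of those that did not pass 74 gained one, 34 with quantile normalization and 30 with 1 library left out. Leaving out 1 library lost 529 of 1974 calls, only the libraries compared 77 of 225, the replicate block 48 of 277, no filter on low values 35 of 194 and total counts 21 of 83. A pseudocount of 0.1 lost 7 of 194, quantile normalization 4, a pseudocount of 5 and robust moderation 1 each, and DESeq2 3 of 79. DESeq2 size factors and no count filter lost 0 of 83 and the fit without MER11B 0 of 82. Where no reason is given for a changed value, the cause was not tested.

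Quantile normalization gave 2470 genes for TAG, 1904 for KO1, 1348 for KO2 and 318 for both knockouts, against 1120, 802, 881 and 101 as deposited. Replicate numbers were not taken to pair the libraries, since not every pair of 1 number correlated over 0.1. Libraries of the same number in different groups had a median correlation of their deviations of -0.03 for genes and -0.04 for repeats of the knockout table, and -0.01 and 0.00 in the hairpin table, with 1, 5, 1 and 4 of 18 pairs over 0.1, where libraries of different numbers had 5, 2, 0 and 10 of 36. Among the 6 pairs of groups in each table, every library correlated best with its own number only for repeats of KO1 and KO2 (0.0932, 0.138 and 0.171), a hint from the data and not the design. With the replicate block 730 genes changed in TAG, 459 in KO1, 583 in KO2, 57 in both knockouts, 34 with SH1, 85 with SH3 and 16 with all hairpins, and PIWIL1 in KO1, at -0.49, no longer passed (limma adjusted p = 0.087). The block left 10 gene lists in the mean of the knockouts, without the histones (adjusted p = 0.058), and 10 transposon lists, and in that of the hairpins 6 and 4. With no filter on low values PIWIL1 in KO1 was also lost at -0.49 (limma adjusted p = 0.066), where more genes were tested.

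With only the libraries compared, fewer libraries set the spread. Then 475 genes changed in KO2, 58 in both knockouts, 8 with SH1, 11 with SH2 and 4 with all hairpins, and PIWIL1 with SH3 passed at -0.97 (limma adjusted p = 0.0087), as SH2 replicate 3 was out of that fit. For transposon families the counts were 145 in TAG, 18 in KO1, 5 in both knockouts, 16 with SH2 and 20 with SH3. With TAG as the control 1864 genes changed in KO1, 3457 in KO2 and 908 in both, and 60, 192 and 37 families. PIWIL1 with SH2 stood at -3.26 with a pseudocount of 0.1 and at -1.28 with 5, values that the library listed at 0 makes depend on the pseudocount. Without SH2 replicate 3 PIWIL1 passed with SH1 at -1.41 (limma adjusted p = 0.011) and with SH3 at -0.97 (limma adjusted p = 0.034). DESeq2 gave 70 families in KO1, 14 with SH1 and 12 with SH3, and total counts gave 81 in KO1, 4 in both knockouts and 352 with SH2. With an estimated correlation 0 gene lists passed in the mean of the knockouts and 1 in that of the hairpins, against 11 and 6 with the preset 0.01, and 1 and 0 transposon lists, against 7 and 6. The mean contrasts shared 3 higher and 5 lower genes between the experiments, against 1 and 1. For 26 to 31 nt the sRNA mean was 5.78%, for 25 nt or more it was 8.49%, and for 28 to 33 nt the means were 2.38% in sRNA and 10.96% in IP.

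Leaving out 1 library leaves fewer libraries in the fit. The gene count for TAG ranged from 536 (without WT replicate 1) to 927, with only TAG replicate 3 moving it by less than 1.5 times. For KO1 it ranged from 367 (WT replicate 1) to 453, and every library moved it that far. For KO2 it ranged from 421 (WT replicate 1) to 963 (KO2 replicate 3), with 437, 497 and 520 without WT replicate 2 and KO2 replicates 1 and 2, and for both knockouts from 42 (WT replicate 1) to 102 (KO2 replicate 3), with 48, 51, 56 and 54 without WT replicate 2, KO1 replicates 1 and 2 and KO2 replicate 1. The counts ranged from 15 to 70 for SH1, 69 to 187 for SH2, 60 to 106 for SH3 and 9 to 43 for all hairpins, each lowest without CTRL replicate 3. Only SH1 replicate 1 for SH1, SH2 replicate 1 for SH2, and SH1 replicate 1 and SH2 replicates 1 and 3 for all hairpins left these within 1.5 times. PIWIL1 ranged from -0.51 to -0.47 in KO1, where every library ended the call, and from -0.34 to -0.0711 (without KO2 replicate 2) in KO2. With the hairpins it ranged from -1.58 to -1.20 for SH1, from -2.81 (SH2 replicate 2) to -1.04 (SH2 replicate 3) for SH2 and from -1.001 to -0.96 for SH3.

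Transposon families ranged from 28 (WT replicate 1) to 72 for TAG, where only WT replicate 2 left the count within 1.5 times. For KO1 they ranged from 14 (KO1 replicate 1) to 42, with 15, 20 and 17 without WT replicates 1 and 3 and KO1 replicate 2. For KO2 they ranged from 17 (WT replicate 1) to 55 (KO2 replicate 3), with 18 without KO2 replicate 1, and for both knockouts from 4 (KO1 replicate 2) to 13 (KO2 replicate 3), with 5 without WT replicate 3. For SH1 they ranged from 0 to 1 by edgeR (1 without CTRL replicate 1), for SH2 from 9 (SH2 replicate 3) to 98 (SH2 replicate 1), with 14, 73, 10 and 12 without CTRL replicates 1, 2 and 3 and SH2 replicate 2, and for SH3 from 0 to 16 (CTRL replicate 2). Without KO2 replicate 2, 12 transposon lists passed in the knockouts, against 7, and without SH2 replicate 3, 3 passed in the hairpin table, against 6. The difference between IP and sRNA in 24 to 32 nt reads ranged from -0.667 points without IP library 2, where it reversed, to 18.8 without sRNA library 1, and was 0.409 without sRNA library 2. Depth limits the repeats of the hairpin table, whose libraries held 1127757 to 2116262 repeat counts against 5491844 to 7574227 in the knockout table, and the depth behind TPM is unknown.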

Other observations

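The genes and repeats named here were chosen, and the list tests between KO1 and KO2 read, only after the results were seen. Among genes changed in both KO1 and KO2, 61 went opposite ways, 46 higher in KO1 and lower in KO2 and 15 the reverse. DPEP1, at 49.3 TPM in WT, stood at 4.57 ± 0.48 TPM in KO1 and 74.1 ± 7.73 in KO2 (SD, n = 3). FLNA stood at 51.0 TPM in KO1 and 8.50 in KO2, and the metallothionein MT2A at 15.4 and 2.10, with 6.19 in WT. AMOTL2, a regulator of YAP, stood at 18.4 and 2.42 TPM, and OAF at 2.10 and 18.9 TPM. TESC, a calcium-binding protein, was higher in the mean of the knockouts by 1.69 ± 0.15 and fell by 1.70 ± 0.26 in the mean of the hairpins (SE, limma adjusted p = 1.8e-04 and 0.0073).

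Set directly against each other, the knockouts differed in several of the fixed lists. Higher in KO1 than in KO2 were 11 of 24 stress genes of the unfolded protein and amino acid responses (12 adjusted over the list alone), among them the serine synthesis enzyme PSAT1 at 163 and 68.1 TPM and the stress sensor SESN2 at 13.7 and 5.12 TPM. The same held for 14 of 30 interferon response genes (16 adjusted over the list alone), such as MX1 and SAMD9, and for 13 of 22 p53 targets with 1 lower (15 and 1 adjusted over the list alone), such as CDKN1A at 9.13 and 4.42 TPM. It also held for 12 of 28 immediate early genes (16 adjusted over the list alone), such as KLF2, and for 6 of 14 NF-kB and inflammatory genes (6 adjusted over the list alone), CSF2 among them at 5.43 and 0.26 TPM. Colon epithelium genes were higher in 5 of 23 cases and lower in 10 (6 and 10 adjusted over the list alone). Of these, AGR2 was lower in KO1 (110.1 TPM against 207 in KO2), as was the goblet cell peptide SPINK4 (-1.95 ± 0.30), and TFF3 was higher by 1.02 ± 0.10. The camera tests gave adjusted p = 4.1e-04, 0.0028, 0.0062, 0.015, 0.0028 and 3.8e-06 in this order, and adjusted p = 0.73, 0.82, 0.73, 0.86, 0.62 and 0.68 with an estimated correlation. The 4 markers of other cell types were lower in KO1 as a list (adjusted p = 3.7e-08, and adjusted p = 0.0060 with an estimated correlation). CD68, LYZ and HBA1 passed singly, CD68 at 20.8 TPM in KO1 and 59.0 in KO2 and LYZ at 477 and 939.7 TPM, and LYZ is also made by intestinal epithelium. Heat shock genes were lower in KO1 as a list, with 1 of 13 lower, HSPH1 (also 1 adjusted over the list alone, adjusted p = 4.1e-04, and adjusted p = 0.68 with an estimated correlation). All 8 lists kept their direction and passed after quantile normalization.

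Repeats other than transposons were also counted. Of 67 such repeats tested in the knockout experiment, 6 were higher and 2 lower in TAG, 3 lower in KO1, and 2 higher and 1 lower in KO2, by edgeR. Of 52 tested in the hairpin experiment, 1 was lower with SH1, 3 with SH2 and 1 with SH3. The centromeric satellite ALR/Alpha was higher in KO2 by 0.53 and in TAG by 0.39, and it fell by 0.53 in the mean of the hairpins (edgeR adjusted p = 3.0e-04). HSAT4 was higher in TAG by 0.81, and it fell by 0.70 in KO1 and by 0.67 in the mean of the hairpins.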
